A study of Mus musculus with 3 samples.

How the data were processed

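Single-cell RNA sequencing measured the marrow niche of mice in 3 libraries, 1 per genotype, all of strain C57Bl/6JCrl and all from animals given tamoxifen by gavage, per the labels. The WT library came from wild-type mice, the FLOX library from mice with floxed Vegfc and no Cre named in the label, and the VC library from mice with floxed Vegfc and Cdh5-CreERT2, a Cre recombinase driven by the promoter of VE-cadherin (Cdh5) and activated by tamoxifen. Per the labels' protocols, tibial marrow was flushed and digested, red cells were depleted, endothelium was marked by intravenous antibody against VE-cadherin, and cells were stained for CD45, Ter119 and LepR. The gates, the mixing proportions of LepR-positive and endothelial cells and the number of mice behind each library are not given in the sources used here. Libraries were made with the 10x Chromium 3' kit v3.1 and sequenced on a NovaSeq 6000.

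The deposited files hold raw UMI counts (unique molecular identifiers, 1 per captured transcript) per gene and barcode, whole numbers that had not been normalised, in a filtered matrix per library. The submitters' processing notes name Cell Ranger 2.1.1, Seurat 3.1 and the build mm10, while the matrix headers give software version 3.1.0, so the version that made the counts is uncertain. Each matrix lists 31053 genes by Ensembl identifier and symbol, and 35 symbols are shared by several identifiers; sums were kept per identifier. No cell annotation was used here. The WT, FLOX and VC files hold 5718, 6529 and 3377 barcodes, against an aim of 3000 to 5000 cells per sample in the design text. Their totals are 56853574, 61758462 and 37361779 UMIs, and the lowest barcode has 500 UMIs in each.

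Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were used, 12790 of 15624 barcodes. Scrublet was run in each library with an expected doublet rate of 6% and called 10 of 4318 WT, 72 of 5734 FLOX and 9 of 2738 VC cells, or 0.232%, 1.26% and 0.329%. Calls this few leave doublets among the cells, and a setting that also left out the 5% of cells with the highest doublet scores was added after the data had been seen. The 12699 cells left were scaled to 10000 UMIs, log-transformed and reduced to 30 principal components of 2000 variable genes chosen across libraries. Leiden clustering on 15 exact neighbours at resolution 1 gave 21 clusters, with no integration of the libraries.

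Marker genes of 17 broad classes and of sinusoidal and arterial endothelium were fixed before the data were examined. The scoring rule was set after the clusters had been seen and was revised several times, for the fit of markers to clusters and not for differences between groups. A cluster took the class with the highest mean log2(CPM + 1) of its markers relative to the mean over clusters, times the share of those markers detected in at least 10% of cells. It stayed unnamed with under 3 detected markers, with more markers of another class among its 10 leading genes (or as many, from 2 up, with the other class's first), or with low depth and none of its own among them. Leading genes were ranked by fold against cells of other classes with a pseudocount of 10 CPM (UMIs of a gene scaled to a common total) among genes at 50 CPM or more. These rules left 2 clusters unnamed, 1 led by Elane, Mpo, Prtn3 and Ctsg and 1 led by Dcn, Col3a1 and Col1a1, together 3.69% of WT, 2.93% of FLOX and 3.37% of VC cells. Endothelial-like clusters were split into sinusoidal-like and arterial-like ones by the same mean of the subclass markers. The word "like" marks names that rest on markers alone.

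Raw UMIs were summed per library and class, and levels are given as CPM of the class total. With 1 library per genotype there is no replicate, so no test was run and no p-value or standard error is given; cells are not replicates. Sums carry exact Poisson intervals and shares carry exact Clopper-Pearson binomial intervals at 95%, and both cover counting error only, not the spread between animals or preparations. A count of 0 stands at a floor of 3 UMIs in ratios. A rule of size took genes with a mean of at least 50 CPM and at least 50 UMIs over the 3 libraries that were at least 1.5-fold higher, or lower, in VC than in WT and in FLOX and by more than FLOX and WT differed. The same count with WT or with FLOX in the place of VC describes how far any single library stands from the others. Named genes are Vegfc, the 12 with the largest smaller ratio in each direction, members of the fixed lists with the largest such ratios, and Cxcl12, Kitl, Flt4, Kdr, Lepr and Adipoq. Mitochondrial, ribosomal protein, immunoglobulin and sex-linked genes and the lists of free-RNA markers were left out of that ranking. Other genes named, among them Angpt1, Ifi27, Fcgr2b, Gadd45a, Fbln5, Sox17 and Atf3, were chosen after their values had been seen.

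The 28 gene lists fixed beforehand cover VEGF ligands and receptors, VEGF-C processing, pan-endothelial, sinusoidal and arterial genes, niche factors, adipocyte, osteogenic and LepR stromal identity genes, interferon response, inflammation and adhesion, antigen presentation by class II, immediate early and dissociation genes, heat shock, hypoxia and glycolysis, Notch, TGF-beta and BMP, p53 and apoptosis, cell cycle, basement membrane, scavenging and lipid uptake, oxidative stress, the respiratory chain, free-RNA markers of erythroid, neutrophil, B lineage and platelet cells, and sex-linked genes. For each list with at least 3 members at a mean of 10 CPM, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these libraries. List members were called past the size by the fold conditions of the rule alone, from a mean of 10 CPM. Such members need not meet its minimum of 50 CPM and are not all among the genes it counted. Shares of cells with a UMI of a gene set were compared after each cell had been thinned to 2000 UMIs.

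The statistics were tested on simulated data before use, with Poisson counts drawn from the pooled profile and the real totals and 200 genes altered in VC. In endothelial-like cells, with 3426 genes past the level minimum, 49 of 50 genes raised 2-fold and 50 of 50 raised 3-fold were recovered, with 44 of 50 lowered 2-fold and 40 of 50 lowered 3-fold. In stromal-like cells, with 3319 genes, the numbers were 50 and 50 for raised and 42 and 39 for lowered genes. All missed genes had fallen below the minimum level, and no unaltered gene passed. These draws hold no biological spread.

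Alternatives fixed before the data were examined were a stricter cell filter (1000 genes, 5% mitochondrial), a looser one (200 genes, 20%), no doublets left out, Leiden resolutions of 0.5 and 2, median-of-ratios scaling, a total without free-RNA, mitochondrial and ribosomal genes, equal weight for each cell, sinusoidal-like cells alone, a fold of 2, lower minimum levels, list members from 50 CPM, and thinning to 1000 UMIs or not at all. Added later were the doublet setting above, VC against each control alone, and endothelial-like cells without those holding 10 or more Adipoq UMIs. The computation used Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. The position of Vegfc is from GENCODE vM21 (GRCm38).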

Results

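The study profiled endothelial cells and LepR-positive stromal cells, the perivascular cells that supply blood stem cells with Cxcl12 and stem cell factor, from the marrow of mice with and without a Cre recombinase meant to delete floxed Vegfc in endothelium. Vegfc encodes vascular endothelial growth factor C, a ligand of the receptors VEGFR3 (Flt4) and VEGFR2 (Kdr). Each genotype was 1 library, so the values below compare 3 libraries and have no replicate check. After filtering, 4308 WT, 5662 FLOX and 2729 VC cells remained, with medians of 10387.5, 8634.5 and 10894 UMIs and 3400, 2930 and 3347 genes per cell. Intervals in parentheses are 95% and cover counting error only.

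Endothelial-like cells made up 72.7% of WT (71.3 to 74.0), 61.4% of FLOX (60.1 to 62.7) and 66.1% of VC cells (64.3 to 67.9). LepR stromal-like cells, marked by Cxcl12, Adipoq and Esm1, made up 6.01% of WT (5.32 to 6.76), 19.4% of FLOX (18.4 to 20.4) and 16.1% of VC cells (14.7 to 17.5). VC lay between the controls for the endothelial-like share and closer to FLOX than to WT for the stromal-like share. Haematopoietic-like cells together held 17.6%, 16.3% and 14.4% in the same order, although CD45 had been stained. Their makeup differed between the controls: B lineage-like cells were 8.54% of WT, 2.86% of FLOX and 3.77% of VC cells, erythroid-like cells 3.53%, 0.247% and 0.953%, and plasma cell-like cells 0.627%, 4.89% and 3.55%. Progenitor-like cells, led by Meis1 and Hlf, were 0.186%, 3.603% and 0.953%, neutrophil-like cells 3.76%, 4.203% and 4.84%, and basophil and mast-like cells 0.975%, 0.459% and 0.366%. The neutrophil-like cluster also held the endothelial gene Cdh5, at 71.2, 450 and 497 CPM in WT, FLOX and VC. Its shares, and the haematopoietic-like total, may therefore include mixed droplets and need not count like cells in each library. The labels give no gate proportions, and the sort can set these shares.

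**Figure D1:**
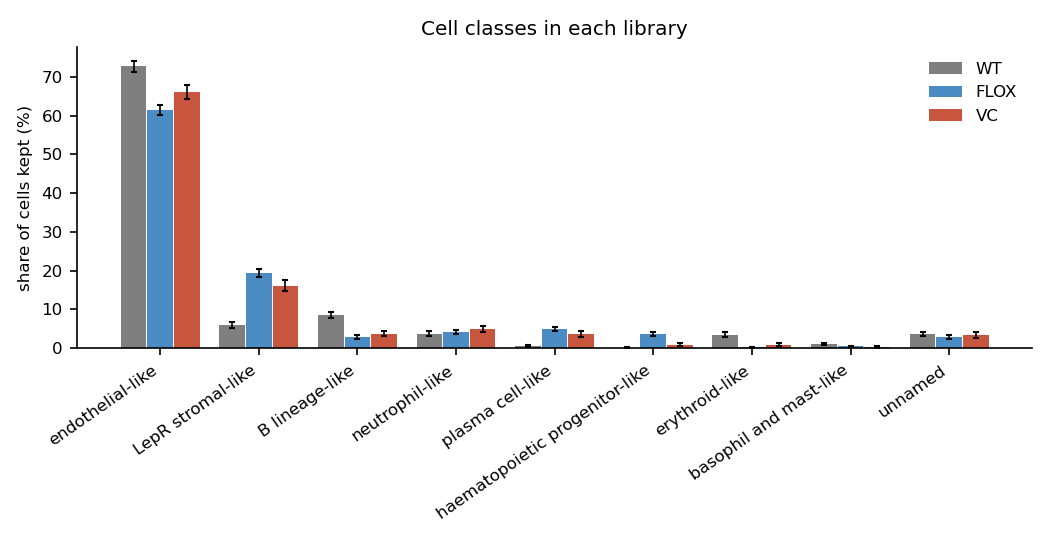
Share of kept cells (%, vertical axis) in each class, named from fixed markers, with 1 bar per library (grey WT, blue FLOX, red VC) and exact 95% binomial intervals as error bars. Endothelial-like cells are the most frequent class in each library, and the LepR stromal-like share is 6.01% in WT against 19.4% in FLOX and 16.1% in VC.

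Within the endothelium, sinusoidal-like cells, which carry the scavenger receptors Stab1 and Stab2 and Flt4, were 92.6% of endothelial-like cells in WT (91.6 to 93.5), 89.4% in FLOX (88.4 to 90.4) and 89.7% in VC (88.3 to 91.1), and at a Leiden resolution of 0.5 they were 85.4%, 81.9% and 85.5%. Arterial-like cells were 7.44%, 10.6% and 10.3%. Neither the gap between WT and VC nor the closeness of FLOX and VC held at both resolutions. The most frequent endothelial-like cluster differed between the libraries. In WT it was led by Slc7a2, Cxadr and Mmrn1 (26.9% of its endothelial-like cells), in FLOX by Ighm, Hspa1b and Ackr1 (30.4%) and in VC by Cxcl9, Cxcl10 and Cd74 (47.7%). A UMI of Mki67 or Top2a, genes of dividing cells, was found after thinning to 2000 UMIs in 2.32% of WT (1.81 to 2.92), 2.38% of FLOX (1.89 to 2.95) and 1.62% of VC endothelial-like cells (1.08 to 2.33). These intervals overlapped, and no difference was detectable at this depth and resolution. Thinning left out 111, 112 and 77 shallower cells. The shares without thinning, which depth can also affect, were 7.60% (6.70 to 8.59), 4.95% (4.25 to 5.72) and 4.21% (3.33 to 5.24). There the WT interval lay above those of FLOX and VC. Depth alone does not order these shares, since VC had a greater median depth than FLOX but no higher share. Stromal-like cells had 0%, 0.912% and 0.683% after thinning, which may include dividing stromal cells. Free RNA or doublets with dividing B lineage-like cells were not separated from division in either class. The median depths were 11160, 11369.5 and 13318 UMIs in stromal-like cells against 10729, 7296 and 9996 in endothelial-like cells.

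Vegfc (ENSMUSG00000031520; chromosome 8, 54077606 to 54187096 on the forward strand of GRCm38) was carried mainly by stromal-like cells in each library. Its level there was 244 CPM in WT (227 to 262; 761 UMIs), 202 CPM in FLOX (194 to 210; 2687 UMIs) and 154 CPM in VC (145 to 165; 965 UMIs). In endothelial-like cells, the class in which Cdh5-CreERT2 acts, it was 1.73 CPM in WT (1.34 to 2.20; 67 UMIs), 1.90 CPM in FLOX (1.43 to 2.46; 56 UMIs) and 0.421 CPM in VC (0.193 to 0.7995; 9 UMIs). Arterial-like cells held 9 UMIs in WT, 9 in FLOX and 0 in VC, where the floor of 3 UMIs is 1.42 CPM and the interval reaches 1.75 CPM. A UMI of Vegfc was found in 2.04%, 0.834% and 0.388% of endothelial-like cells, against 83.4%, 78.8% and 72.0% of stromal-like cells. Of the 56 FLOX UMIs, 31 sat in 5 cells with at least 10 UMIs of the stromal gene Adipoq, and without such cells FLOX stood at 0.8502 CPM (0.550 to 1.26), WT at 1.73 and VC at 0.375 CPM (0.162 to 0.739). The 3' tags of this assay come from the last exon, whose untranslated part spans 54186066 to 54187096, and the exon flanked by loxP sites is not given in the sources used here, so these counts may not read the deletion. Neutrophil-like cells held 0 UMIs in WT, 41 in FLOX and 43 in VC, or 0, 9.90 and 16.5 CPM, with a floor of 1.31 CPM and an interval up to 1.61 CPM in WT. The stromal genes Cxcl12 and Adipoq differed alike there, at 15.7, 1355 and 2515 CPM and at 0.874, 74.6 and 116 CPM, so these UMIs are not read as neutrophil expression. Plasma cell-like cells, of similar or greater depth, held 0 UMIs in each library.

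**Figure D2:**
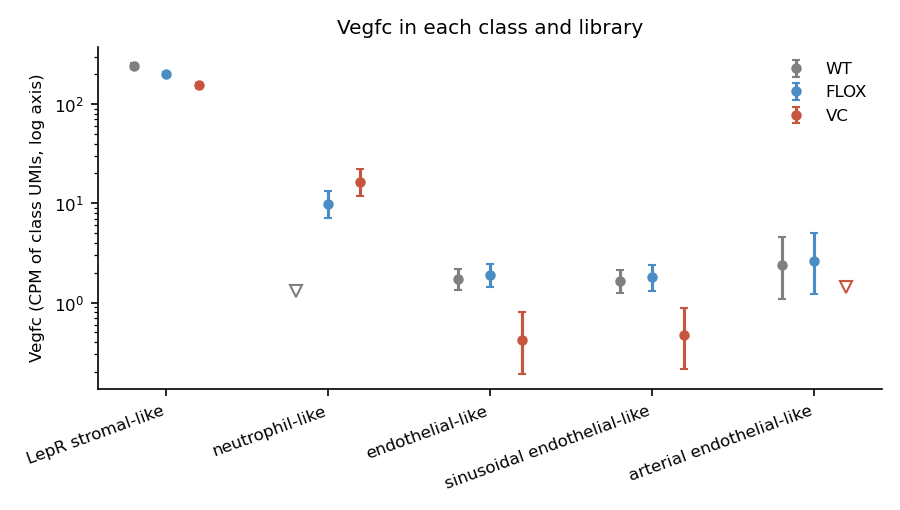
Vegfc level (CPM of class UMIs, log axis) in 5 classes, 1 point per library with an exact 95% Poisson interval; open triangles mark a count of 0 at the floor of 3 UMIs. Stromal-like cells lie between 154 and 244 CPM and endothelial-like cells between 0.421 and 1.90 CPM.

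The comparison of VC endothelial-like cells with both controls asks what differs in the library in which Cdh5-CreERT2 was present with floxed Vegfc. The leading genes were those induced by interferon. Cxcl9 and Cxcl10, chemokines that attract T cells, stood at 3524 and 678 CPM in VC against 212 and 26.6 in WT and 168 and 51.8 in FLOX. The guanylate-binding proteins Gbp2, Gbp4, Gbp5 and Gbp7 and the immunity-related GTPases Igtp and Iigp1, which act against pathogens inside cells, were 5.24 to 10.7 times their level in the nearer control; Iigp1, for example, was at 2317 CPM against 381 and 352. Genes of antigen presentation by class II, normally abundant in professional antigen-presenting cells, were low in both controls and higher in VC: Cd74, the invariant chain, was at 480 CPM (3.88 in WT, 15.2 in FLOX), H2-Aa at 159 CPM (2.09 and 5.35) and H2-Ab1 at 134 CPM (3.80 and 11.9). The protease inhibitor Serpina3f was at 394 CPM against 58.5 and 74.1.

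By the rule of size, 61 of 3424 genes were higher in VC than in both controls and 2 were lower. With WT as the odd library the numbers were 23 and 18, and with FLOX 2 and 3. The 2 lower genes were Itih5, at 77.4 CPM in VC against 136 and 142, and the butyrophilin-like gene Btnl9, at 415 CPM against 676 and 644. Against WT alone 99 genes were higher and 46 lower, and against FLOX alone 78 and 8. These are counts of genes past a size in single libraries. Sinusoidal-like cells alone gave 59 higher and 3 lower of 3403 genes, and arterial-like cells 74 and 5 of 3570.

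**Figure D3:**
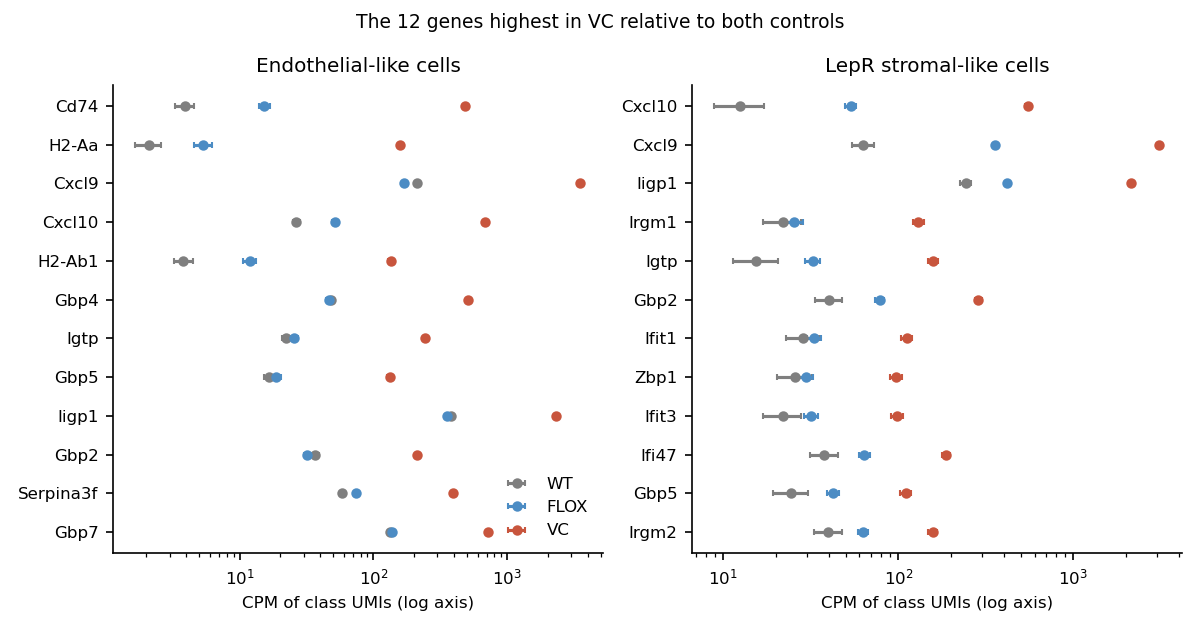
Levels (CPM of class UMIs, log axis) of the 12 genes with the largest smaller ratio of VC to WT and to FLOX, in endothelial-like cells (left) and LepR stromal-like cells (right), 1 point per library with exact 95% Poisson intervals, many narrower than the points. VC lies to the right of both controls for each gene shown.

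Of the interferon response list, 16 of 17 measured members were at least 1.5-fold higher in VC endothelial-like cells than in both controls and none was lower. With the rule's minimum of 50 CPM, 9 members were among the 61 higher genes. The list's median log2 ratio was 1.45 for VC/WT and 1.66 for VC/FLOX, each above all 10000 matched random lists, and -0.05 for FLOX/WT (percentile 69.4). Besides Cxcl10 and Gbp2, B2m, the light chain of class I molecules, stood at 2641 CPM against 1325 and 1370. Ifi27 alone among the measured members was not past the size, at 127 CPM against 106 and 129. All 4 measured class II genes were higher, with medians of 6.12 for VC/WT and 4.86 for VC/FLOX, and FLOX/WT was 1.499. The sinusoidal-like and arterial-like parts both showed the interferon list higher, with VC/WT and VC/FLOX medians of 1.42 and 1.90 in the former and 1.5015 and 1.30 in the latter.

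Among the genes of the Vegfc pathway, the receptor Flt4 was at 667 CPM in WT, 702 in FLOX and 783 in VC, and Kdr at 1916, 1751 and 1558. None of the 7 measured VEGF ligands and receptors passed the size, with medians of -0.01 (VC/WT) and -0.04 (VC/FLOX), nor did the 3 measured genes of VEGF-C processing (0.41 and 0.02; Ctsd 392, 487 and 540 CPM). None of the 14 pan-endothelial genes passed (medians -0.16 and -0.03; Erg 95.1, 82.0 and 69.8 CPM), nor of the 8 sinusoidal genes (0.15 and 0.11), where Adamts5 was at 2769, 2958 and 3860 CPM. Of 11 arterial genes, Ly6a, which encodes the surface marker Sca-1, was higher, at 916 CPM against 238 and 378, while the list's medians went apart, 0.60 against WT and -0.21 against FLOX. Scavenging and lipid uptake had medians of -0.39 and -0.15, below nearly all random lists (percentiles 0.01 and 0.20), without a member past the size; Fabp4, a fatty acid carrier, was at 11913, 11164 and 8705 CPM, while the Fc receptor Fcgr2b was at 525, 599 and 836 CPM.

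Stress-related lists differed between the controls too. Heat shock genes had medians of 0.56 for VC/WT, 0.27 for VC/FLOX and 0.40 for FLOX/WT, with Hspa1a at 145, 275 and 391 CPM in WT, FLOX and VC, and immediate early genes 0.11, 0.40 and -0.39, with Klf2 at 239, 269 and 396 CPM. Of the p53 and apoptosis list only Cdkn1a, an inhibitor of the cell cycle, was past the size in VC, at 144 CPM against 71.6 and 73.1 (medians 0.02 and 0.07). The VC/WT and VC/FLOX medians were 0.29 and -0.01 for niche factors, 0.16 and -0.02 for adipocyte genes, 0.29 and -0.23 for stromal identity, 0.22 and -0.94 for 3 osteogenic genes, 0.19 and -0.13 for inflammation and adhesion, 0.05 and 0.06 for hypoxia and glycolysis and 0.04 and -0.10 for Notch. They were -0.05 and 0.10 for TGF-beta and BMP, -0.08 and -0.10 for cell cycle, -0.06 and -0.12 for basement membrane, -0.04 and -0.08 for oxidative stress, -0.03 and 0.07 for the respiratory chain and -0.26 and -0.06 for sex-linked genes. No member of these lists passed the size. Median-of-ratios scaling shifts all VC/WT values by 0.13 and all VC/FLOX values by 0.05 in both classes. Medians no larger than these shifts therefore have no firm sign.

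Markers of other cells differed between the libraries in endothelial-like cells. Haemoglobin genes had medians of -2.02 (VC/WT), 0.81 (VC/FLOX) and -2.80 (FLOX/WT), neutrophil granule genes -1.21, -0.44 and -0.76, and B lineage genes 0.98, -1.50 and 2.55. Ngp and Camp met the fold conditions downward but lay below the rule's minimum of 50 CPM. The platelet list had 1 measured member, Pf4, at 15.3 CPM in WT, 19.9 in FLOX and 28.6 in VC. Genes of the stromal list were also present, with Cxcl12 at 76.4, 268 and 165 CPM in WT, FLOX and VC, Kitl at 19.6, 65.5 and 43.9, Adipoq at 1.47, 7.25 and 2.34 and Lepr at 53.9, 43.5 and 39.8. Cxcl12 stood at 353, 1159 and 968 CPM in arterial-like cells against 46.5, 151 and 76.8 in sinusoidal-like cells. Cxcl12 therefore cannot be read as RNA of stromal cells alone. The same holds for Kitl, which was higher in arterial-like cells than in endothelial-like cells together and was among the leading genes of an arterial-like cluster within the class. Lepr was highest in WT, where Cxcl12, Kitl and Adipoq were lowest. It was among the leading genes of a sinusoidal-like cluster within the class under the stricter cell filter, but its source was not tested.

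LepR stromal-like cells, a class outside the endothelium that Cdh5-CreERT2 targets, also differed between VC and both controls in interferon-induced genes. Cxcl10 was at 550 CPM in VC against 12.5 in WT and 53.5 in FLOX, and Cxcl9 at 3068 against 62.9 and 356. Iigp1 was at 2138 CPM against 242 and 419, Irgm1 at 130 against 21.8 and 25.5, and Igtp at 158 against 15.4 and 32.4. The antiviral genes Ifit1, Ifit3 and Zbp1 were 3.38, 3.104 and 3.28 times their level in the nearer control, and Gbp2, Gbp5, Ifi47 and Irgm2 were 3.66, 2.59, 2.92 and 2.495 times. For Cxcl9 and Cxcl10 FLOX itself stood above WT, by 2.501 and 2.0965 on the log2 scale.

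The rule of size gave 35 genes higher and 6 lower of 3355 in VC stromal-like cells, or 30 and 10 with each cell weighted alike. With WT as the odd library, the one with 259 stromal-like cells against 1098 and 439, the numbers were 50 and 110, and with FLOX 8 and 4. Against WT alone 208 genes were higher and 143 lower in VC, and against FLOX alone 54 and 25. Of the interferon list 13 of 18 members were higher by the fold conditions and none lower, and 9 members were among the 35 higher genes. Its medians were 1.62 for VC/WT and 1.14 for VC/FLOX, above all random lists. The FLOX/WT median was 0.49, above all random lists as well. Of the 2493 genes tested in both classes, 41 were higher in VC in endothelial-like and 24 in stromal-like cells, and 21 were in both, where independent lists would share 0.395. The 21 include Cxcl9, Cxcl10, Iigp1, Igtp, Irgm1, Irf1 and the peptide transporters Tap1 and Tap2. The counts come from different cells of the same 3 libraries.

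The 6 lower genes in VC stromal-like cells were Fabp4 (149 CPM against 536 in WT and 625 in FLOX), the neutrophil chemokine Cxcl1 (37.6 against 73.5 and 74.0), Tfpi (68.2 against 210 and 120), Map1b (152 against 259 and 247), Id1 (31.7 against 51.7 and 69.7) and Pparg, a regulator of fat cell formation (47.5 against 73.5 and 72.7). Fabp4 and Tfpi were also among the leading genes of endothelial-like clusters. Genes of endothelium were lower as groups, by the fold conditions from a mean of 10 CPM. They were 8 of 10 pan-endothelial genes (medians -1.87 and -1.30), 5 of 8 sinusoidal genes (-1.72 and -1.27) and 6 of 12 scavenging genes (-1.67 and -1.01), with Kdr at 71.9, 43.0 and 15.2 CPM and Flt4 at 25.7, 21.6 and 7.52. These levels were a few percent of those in endothelial-like cells, with medians over 19 endothelial genes of 4.28% in WT, 3.04% in FLOX and 1.06% in VC. They also differed between settings: the smaller pan-endothelial ratio was -0.37 with no doublets left out and -0.15 with a looser cell filter, and in both a cluster led by Cenpf, Prc1 and other division genes joined the class.

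Factors for which these cells are known were measured at high levels in each library. Cxcl12 was at 26075, 24098 and 25618 CPM in WT, FLOX and VC, Kitl (stem cell factor) at 2999, 2516 and 2415, Adipoq at 1132, 1326 and 1290 and Lepr at 2365, 1409 and 1642. Angpt1, a ligand of Tek, was at 370, 245 and 195 CPM. No member of the niche factor list (15 measured; medians -0.07 and -0.22, percentiles 19.1 and 0.04) or of the stromal identity list (18 measured; -0.22 and -0.05, percentiles 0.02 and 24.1) passed the size. Of 15 adipocyte genes, Fabp4, Cd36 and Pparg were lower (medians 0.11 and -0.08), and none of 12 osteogenic genes passed (-0.14 and -0.01; Ibsp 8599, 6811 and 6356 CPM). Fabp4, and Cd36 under the stricter cell filter, were among the leading genes of endothelial-like clusters. Of VEGF ligands and receptors 3 of 9 were lower, the endothelial Flt1, Flt4 and Kdr (-0.28 and -0.35), and the VEGF-C processing genes, among them Ccbe1 at 137, 121 and 119 CPM, had medians of -0.19 and -0.04. Sele, Selp and Cxcl1 were the 3 of 13 inflammatory genes lower in VC (0.04 and -0.37). Sele and Selp were among the leading genes of endothelial-like clusters, so admixed endothelial RNA may set their level.

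The other lists in stromal-like cells had VC/WT and VC/FLOX medians of 0.20 and 0.24 for arterial genes, 0.24 and 0.06 for immediate early genes, 0.89 and -0.10 for heat shock, 0.22 and 0.02 for hypoxia and glycolysis, -0.47 and -0.26 for Notch and -0.06 and -0.12 for TGF-beta and BMP, where Id1 was the member past the size. They were 0.05 and -0.04 for p53 and apoptosis, where Gadd45a was the member past the size (23.2 CPM against 11.6 and 14.7), 0.09 and 0.11 for cell cycle, -0.11 and -0.15 for basement membrane, 0.14 and -0.03 for oxidative stress, 0.36 and 0.13 for the respiratory chain and -0.48 and -0.07 for sex-linked genes. Of class II genes 2 were measured, of which H2-Eb1 was past the size, at 5.46, 9.09 and 15.5 CPM, and Cd74 was not, at 2.89, 21.6 and 23.2. Free-RNA markers again differed between the controls, with medians for VC/WT, VC/FLOX and FLOX/WT of -4.06, 0.78 and -4.84 for haemoglobin, -0.84, 0.11 and -0.90 for neutrophil granules and 1.84, -2.16 and 3.59 for the B lineage; no platelet gene was measured.

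**Figure D4:**
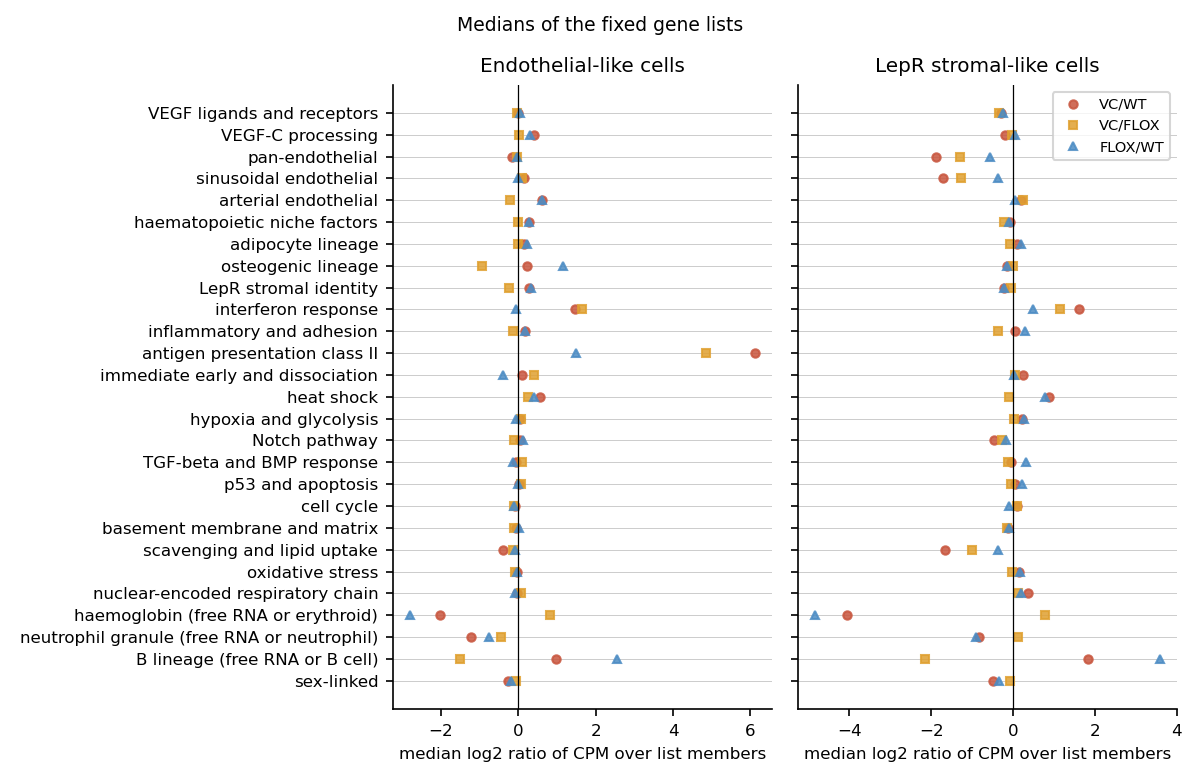
Median log2 ratio of CPM over the members of each fixed list (horizontal axis) in endothelial-like cells (left) and LepR stromal-like cells (right), for VC/WT (circles), VC/FLOX (squares) and FLOX/WT (triangles); lists with under 3 measured members have no point. The interferon response list lies between 1.14 and 1.66 for VC against each control in both classes, with FLOX/WT at -0.05 and 0.49.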

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

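All tests in this part were chosen only after the results had been seen, and the criterion for the Vegfc tests was revised after the values for single genes had been seen. A first criterion, overlap of the interval with the range over all comparison genes, would have counted the WT value among those at the level of RNA from other cells.

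The interferon response list was also higher in VC in classes that the main comparisons do not use. In neutrophil-like cells the smaller of the VC/WT and VC/FLOX medians was 1.6835 (log2), with VC/WT at 2.62 over 17 members, and FLOX/WT was 1.01. Niche RNA differed alike in these cells, with Cdh5 at 71.2, 450 and 497 CPM in WT, FLOX and VC, Cxcl12 at 15.7, 1355 and 2515 CPM and Adipoq at 0.874, 74.6 and 116 CPM, so a response of neutrophils themselves is not shown. In B lineage-like cells the smaller median was 0.649, with VC/FLOX at 1.23 over 10 members, and Cxcl12 was at 146, 77.1 and 457 CPM. Plasma cell-like cells gave -0.28 and 0.45 over 9 members, with 27 WT cells.

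The first pattern weighed is the higher level of interferon response genes in VC. RNA of endothelial cells in stromal droplets is argued against by its size, since the excess over FLOX in stromal-like cells was 80.11% of that in endothelial-like cells (median of 16 members), while 19 endothelial marker genes stood at 1.06% there. A response confined to the endothelium is argued against by the size of the stromal medians, 1.62 for VC/WT and 1.142 for VC/FLOX, against 0.49 for FLOX/WT. Each of these was above all random lists, so the percentile alone does not set VC apart from the gap between the controls. The deletion, the Cre itself, the preparation of the library and another state of the VC animals, such as an infection, cannot be told apart. Only the VC library carries Cdh5-CreERT2, each genotype has 1 library, and no map from cells to animals is given. In VC 34.22% of endothelial-like cells lay above the 99th percentile of the control cells at 2000 UMIs, counted over the list without B2m. The shares of 0.861% in WT and 0.951% in FLOX are small by construction, since their own cells set that cut. Of VC cells 26.8% lay near the cut, a spread over many cells that the deletion, the Cre, the preparation or another state may give.

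The second pattern is Vegfc in endothelial-like cells without those rich in Adipoq. The level expected from stromal RNA was computed from 7 other stromal genes (Cxcl12, Pdgfrb, Angpt1, Il7, Hp, Esm1 and Grem1). Cxcl12 was higher in arterial-like than in sinusoidal-like cells, so it overstates stromal RNA, and the medians below include it. The Vegfc levels it gives, 0.714, 1.88 and 0.907 CPM in WT, FLOX and VC, lay outside the observed interval in each library. The observed level was 0.9337 times the median expected level in FLOX and 0.795 times in VC, so stromal RNA may account for both. In WT it was 3.994 times the median of 0.434 CPM, but the value expected from Il7 alone, 1.62 CPM, lies inside the WT interval and the next highest, 0.714 CPM, does not, so expression by WT endothelium and stromal RNA cannot be told apart. A loss of endothelial Vegfc in VC relative to FLOX was therefore not detectable by these counts. The exon deleted is also not given in the sources used here. VC did lie below WT, at 0.375 CPM (0.162 to 0.739) against 1.73 CPM (1.34 to 2.20), and these intervals do not overlap. FLOX, at 0.8502 CPM (0.550 to 1.26), lay below WT as well, so a level below WT is not particular to the library with Cre.

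The third pattern is the lower level of endothelial genes in VC stromal-like cells. If endothelial RNA or doublets brought these UMIs, the genes would stand at 1 common ratio to their endothelial level within a library. At least 78.95% of the 19 genes lay within 1.5-fold of the median ratio in each library, and the medians were 4.28%, 3.04% and 1.06%, which is consistent with a smaller admixture in VC. Fabp4, which is not among the 19, stood at 4.50%, 5.59% and 1.71%, over 1.5-fold above the median in FLOX and VC, so its lower level in VC stays open. No biological explanation was tested for these genes.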

How the results depend on the processing

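Leaving out the highest doublet scores or the Adipoq-rich cells and setting VC against each control alone were chosen after seeing the data, and the other alternatives were fixed before. No paired analysis was possible because each genotype has 1 library. No value changed sign against both controls together where a direction had been called. The ratio compared was the smaller of VC/WT and VC/FLOX, which has no sign where they differ in direction. A change of sign against 1 control alone was therefore not counted. Of the values that answer a comparison, 121 stayed within their counting interval or within 1.5 times the count and 72 did not; for other named genes and lists the numbers were 818 and 179. Settings on endothelial-like cells alone do not apply to stromal-like cells. Depth limits Vegfc, with 67, 56 and 9 endothelial UMIs, and the stromal-like class of WT, with 259 cells.

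The endothelial-like share of WT was 68.6% with the looser cell filter, and those of FLOX and VC were 59.1% and 63.6% with the stricter one. The LepR stromal-like share of WT was 7.01% with the stricter filter, 6.81% with the looser one, 7.295% with no doublets left out, 6.99% at Leiden resolution 0.5 and 6.97% without the top doublet scores. That of FLOX was 20.6% with no doublets left out and 17.6% at resolution 2, and that of VC 18.1% with the stricter filter and 14.6% at resolution 2. WT stayed lowest under each of these. The sinusoidal-like share in WT, FLOX and VC was 88.7%, 86.6% and 87.1% with the stricter filter, 86.8%, 83.9% and 86.7% with the looser one, 85.4%, 81.9% and 85.5% at resolution 0.5, and 86.0%, 82.7% and 85.1% without the top doublet scores. At resolution 2 it was 88.5% in WT and 87.1% in FLOX. The cause was not tested.

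The share of endothelial-like cells with Mki67 or Top2a was 1.71% in WT and 1.59% in FLOX when thinned to 1000 UMIs, and 7.60%, 4.95% and 4.21% in WT, FLOX and VC without thinning, where fewer or more UMIs were read by construction. It was 1.80% in WT, 1.65% in FLOX and 0.702% in VC at resolution 2, where a cluster led by division genes (24, 22 and 17 cells) was left unnamed. FLOX and VC were at 1.32% and 0.961% with the looser filter and 1.496% and 1.05% with no doublets left out, where such a cluster (20, 29 and 16 cells, and 18, 26 and 16 cells) took the stromal name. WT was at 1.86% with the looser filter and 2.06% with no doublets left out, so VC had the lowest share in these 3 settings. The same settings moved dividing cells out of the endothelial-like class. Whether that move accounts for the lower share in VC was not tested. FLOX was at 1.74% without the top doublet scores, where it lay below VC, and the cause was not tested.

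Counts by the rule of size follow the thresholds by construction. In endothelial-like cells 38 genes were higher and 0 lower at a fold of 2, 115 and 17 from a mean of 10 CPM and 20 UMIs, and 300 and 541 with no minimum CPM. With 1 control fewer, 99 were higher and 46 lower against WT alone and 8 were lower against FLOX alone, and median-of-ratios scaling gave 1 lower. In stromal-like cells the numbers were 18 and 1 at a fold of 2, 74 and 89 from 10 CPM, 221 and 579 with no minimum CPM, 208 and 143 against WT alone and 54 and 25 against FLOX alone, with 10 lower when each cell had equal weight.

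Vegfc in endothelial-like cells of WT was at 2.37 CPM with equal weight for each cell. In FLOX it was at 1.17 CPM with equal weight, 0.8502 without Adipoq-rich cells, 0.826 with the stricter filter, 0.848 with the looser one, 0.822 with no doublets left out, 0.826 at resolution 2 and 0.8502 without the top doublet scores, so its main value rests on the 5 Adipoq-rich cells. VC stayed within its interval under the alternatives run. The smaller of the interferon list's VC/WT and VC/FLOX medians in endothelial-like cells was 1.59 with median-of-ratios scaling and 1.08 with members from 50 CPM, where fewer genes enter. The smaller stromal median was 1.02 with equal weight for each cell and 1.25 with members from 50 CPM.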

Other observations

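No test in this part was planned; the values were looked at after the main comparisons.

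Arterial-like cells, 233 in WT, 367 in FLOX and 185 in VC, differed most between WT and the other libraries. The arterial gene list had medians of 1.37 for VC/WT, 0.11 for VC/FLOX and 1.24 for FLOX/WT. Fbln5, an elastic fibre protein, stood at 37.9 CPM in WT, 317 in FLOX and 313 in VC, and the transcription factor Sox17 at 54.3, 169 and 182. The niche factors Cxcl12 and Kitl stood at 353, 1159 and 968 CPM and at 151, 459 and 365 CPM. A cluster led by Fbln2, Sema3g and Sox17 held 2 WT, 111 FLOX and 51 VC cells, so the kinds of arterial-like cell captured differed between libraries.

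The list of immediate early genes, which tissue dissociation also induces, had medians of 0.80 for VC/WT and 0.71 for VC/FLOX in arterial-like cells, with 7 of 16 members past the size and higher in VC. Heat shock genes had medians of 0.88 and 0.23 in the same cells (percentiles 100 and 99.9), with 1 of 11 members past the size. Atf3, a stress-induced transcription factor, stood at 66.8 CPM against 17.5 in WT and 17.3 in FLOX, and Zfp36 at 297 against 165 and 131. All 7 measured class II genes were past the size there, among them Ciita, the regulator of the class II genes, at 71.6 CPM against 2.92 and 3.82.

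Counts of interferon transcripts and of T cell genes were low in the kept cells. Ifng had 0 UMIs in WT, 0 in FLOX and 3 in VC, and Ifnb1 had 0 in each. Cd3e had 6, 5 and 1 UMIs and Cd3d 35, 38 and 16.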
